A study of Mus musculus with 42 samples.

How the data were processed

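The series holds 42 samples of EpCAM-sorted mouse liver ductal cells. RNA was sequenced in 16 culture libraries (3, 4, 3, 3 and 3 at 0 h, 12 h, 24 h, 48 h and in organoids) and 6 liver libraries (2 each from undamaged liver and after 3 and 5 days of DDC). Modified cytosine and 5hmC were each profiled in 6 liver samples (2 per group), and H3K4me3 (2 samples) and TET1 binding (6) in organoids. Per the labels, all liver RNA came from females, the 5hmC and bisulfite samples from males, and each culture time had 1 female, which the Y-linked gene Eif2s3y matched in number. The labels give no animal numbers, so p-values measure the spread between these samples. For 5hmC day 5 sample 2, 1 label calls the source liver organoids while its title, tissue and description give DDC-damaged liver, and it was used as day 5.

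RNA values are TPM in the tables deposited by the authors, per the file headers; the aligner and counting tool for RNA are not given in the sources used here. Per the submitters' processing notes, reads were mapped to GRCm38.p6 for RNA, bisulfite, RRHP and ChIP data, with Bismark for bisulfite data, Bowtie2 for RRHP data and Bowtie2 2.2.9 with MACS2 2.1.0 for ChIP data. The deposited bisulfite files give, per CpG, counts of modified calls and of all calls, from which the signal used here is the modified share of calls, with both samples of a group merged by the authors. The deposited RRHP files list distinct read starts with a mapping quality score per site and no read counts. The deposited H3K4me3 list carries a score whose meaning the authors do not state, and the deposited TET1 list gives positions only, an other kind of value in units of peaks. That TET1 list is a single list named by all 6 DamID samples.

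Analyses used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and bedtools 2.31.1. RNA tables were tested separately as log2(TPM + 1) for genes at 1 TPM or more in at least 3 (culture, 13286 genes) or 2 (liver, 14048 genes) libraries, by limma with an intensity trend in the prior and Benjamini-Hochberg adjustment, calling an adjusted p under 0.05. Of 31680 listed names, 27 had been turned into dates and were left out (0.0907 to 0.171% of TPM). Culture columns fall in 2 sets whose sizes per time match those of the 2 RNA kits in the labels, and the set was a covariate in place of the kit; that it is the kit is inferred from the numbers. Sex was not in the main culture fits. It was added as a covariate in an alternative, with 1 column per time taken as female from Eif2s3y. Of the 25 gene lists, all but the lymphocyte list in culture (2 genes tested) were tested by camera with a preset correlation of 0.01 and again with an estimated one. Libraries were left out in turn, and groups were split in all ways where 3 or more libraries allow. With 2 against 2 libraries the smallest exact permutation p is 0.333 and with 3 against 3 it is 0.1, so calls rest on the variance that limma shares across genes.

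The gene lists are ductal identity, WNT targets and LGR5 stem-cell genes, fetal-like and regenerative epithelium, YAP/TAZ targets, ErbB ligands and MAPK feedback, DNA methylation and hydroxymethylation enzymes, Polycomb, trithorax and NuRD, S phase, G2/M, immediate-early genes, ribosome biogenesis, p53 targets, glycolysis, cholesterol biosynthesis, NOTCH, inflammation and NF-kB, interferon response, extracellular matrix and integrins, and imprinting and growth. A further 6 hold markers of hepatocytes, endothelium, macrophages, lymphocytes, stellate cells and erythroid cells. Of 25 hepatocyte markers 17 were tested in culture and 24 in liver, and organoids had 13 at 1 TPM or more. For endothelial markers these numbers were 7, 20 and 6, for macrophage markers 6, 15 and 5, for lymphocyte markers 2, 10 and 0, for stellate markers 7, 16 and 5 and for erythroid markers 7, 8 and 1, and no hepatocyte marker is in another list.

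The lists, the main tests and a rule for named genes were fixed before the data were examined, apart from the changes to the 5hmC test described below. Chosen after the data had been seen were the settings that leave out the 2 libraries with few genes, leave-one-out and blocks for gene lists, and for 5hmC all mapping qualities, sites in 2 or more libraries, limma and the Poisson bound. So were the splits of libraries and the tests of explanations, except that of CpG-dense fragments. The rule names 13 fixed genes, up to 4 called members per list with the largest changes at a mean of 5 TPM or more (else up to 2 with the smallest p), and the 8 largest rises and 8 largest falls outside the lists at 10 TPM or more. It gives more genes than the text names. The genes named are a subset of the rule's genes that was picked after their values and leave-one-out results had been seen, mostly genes whose call held, so the named genes look steadier than the full set. In the order 12 h, 24 h, 48 h, organoids, organoids against 48 h, day 3, day 5 and day 5 against day 3, the rule gives 103, 111, 115, 111, 72, 72, 82 and 62 genes, of which 84, 98, 105, 104, 30, 37, 54 and 0 were called and 58, 69, 82, 86, 8, 0, 0 and 0 stayed called without any 1 library. The text names 32, 26, 35, 42, 20, 25, 40 and 4 of them, with 30, 26, 35, 40, 18, 23, 35 and 0 called and 29, 24, 34, 39, 8, 0, 0 and 0 called without any 1 library. Of the 13 fixed genes 4, 6, 7, 8, 0, 2, 3 and 0 were called.

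For 5hmC, read starts with a mapping quality of at least 10 gave the detected CCGG sites. Since the files have no read numbers, the planned test of reads was replaced by a test of the number of detected sites per promoter, peak or gene span with at least 30 sites over the 6 libraries, by edgeR quasi-likelihood with TMM. Its Poisson bound was turned off after the data had been seen, since simulated changes were almost never recovered with it. Per-site tests were not run. Libraries with the same number deviated together from their group means, with correlations of 0.204 (day 3 and undamaged), 0.547 (day 5 and undamaged) and 0.193 (both days) across 7213 promoters and of 0.214, 0.544 and 0.208 across 8633 peaks. This check was made after the fits with a block had been seen, and it does not show that the numbers pair the 5hmC libraries. A trait shared by the libraries numbered 1 would give the same correlations. Library 1 of each group had fewer sites, and in undamaged liver and at day 5 a low share in H3K4me3 peaks. The labels name no shared animal or day. Promoters are 2 kb on either side of the gene end that has an H3K4me3 peak within 2 kb, for genes with such a peak at exactly 1 end (10443), since the annotation has no strand. Modified cytosine was summed over CpGs with at least 5 calls in all 3 files (140729310, 110799952 and 152127303 calls in the undamaged, day 3 and day 5 files, mean coverage 9.06, 7.20 and 9.75) for regions of at least 5 CpGs, and a difference of 0.2 was counted and compared with 20 draws of binomial calls.

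The RNA tests were run on simulated data with 200 changed genes in 5 draws. At a log2 change of 1, 14.6% were recovered for 12 h, 13.2% for organoids, 7.40% for day 3 and 8.60% for day 5, and at a log2 change of 2, 63.0, 51.4, 57.0 and 55.4%, with 6.24, 5.83, 2.99 and 4.19% of calls false. For modified cytosine 132 of 200 planted promoter differences were found. Each CpG was lowered by 0.3 in modified share but not below 0, so the difference of a promoter could be smaller. Alternatives tried were another pseudocount, filter, scaling (TMM-like, quantile), prior, covariate (none, or column set and sex), replicate block, single column sets, pairs of groups fitted alone, and for the marks other mapping quality, coverage, level, overlap and promoter settings.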

Results

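Ductal cells of the adult mouse liver, sorted for the surface protein EpCAM, were profiled in 42 samples. RNA was measured in 22 of them. In culture, sorted cells had spent 10 min (called 0 h here, n = 3), 12 h (n = 4), 24 h (n = 3), 48 h (n = 3) or 6 days (organoids, n = 3) in Matrigel with organoid medium. In the animal, cells came from undamaged liver and from liver after 3 and 5 days of DDC, a dietary toxin that injures bile ducts (n = 2 each). Modified cytosine (bisulfite sequencing, which reads 5mC and 5hmC alike) and 5hmC (RRHP, which detects 5hmC at CCGG sites) were each profiled in 6 samples, 2 per group from undamaged liver and day 3 and day 5 of DDC. Organoids gave 1 H3K4me3 ChIP sample with 1 input, and 6 DamID samples, 3 with TET1 fused to the Dam methylase and 3 with Dam alone. The listed TPM summed to 913390 to 936130 per culture library and 908940 to 916510 per liver library. The culture libraries held 9043 to 12452 genes at 1 TPM or more, and the liver libraries 13010 to 13244. The lowest 2 were 24 h library 1 (9043 genes, against 11316 and 11483 in the other 24 h libraries) and 0 h library 3 (9790, against 11590 and 11739).

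The first comparison asked how the cells changed during 12 h of culture. Cxcl1 and Cxcl2, which encode chemokines that recruit neutrophils, lost most of their transcripts. Cxcl1 fell from 5804 to 458 TPM, a log2 change of -4.04 ± 0.51 (SE, n = 4 at 12 h and 3 at 0 h), and Cxcl2 from 3535 to 315 TPM (-3.83 ± 0.45). Of the 27 inflammation and NF-kB genes, 0 rose, 21 fell and 6 were not called (0 and 23 rose and fell adjusted over the list alone). That list lay -2.56 in median log2 change relative to all genes (camera, adjusted p = 6.97e-20, and adjusted p = 0.0127 with an estimated correlation). Cxcl5 (-3.83 ± 0.40) and the cytokine Lif (-3.20 ± 0.57) were among the fallen members, with Cxcl5 at 333 TPM in 12 h library 1 and 70.0 to 112 TPM in the other 3. Immediate-early genes, which cell dissociation can induce, went the same way, with Fosb at -4.58 ± 0.66, Atf3 at -2.73 ± 0.52, Zfp36 at -2.81 ± 0.56 and Fos at -2.71 ± 0.60. Of the 30 such genes, 0 rose, 17 fell and 13 were not called (0 and 18 rose and fell adjusted over the list alone). Their relative median was -1.28 (camera, adjusted p = 2.96e-11, and adjusted p = 0.114 with an estimated correlation).

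Ductal identity genes were lower as a group at 12 h. Of 25 tested, 2 rose, 13 fell and 10 were not called (3 and 14 rose and fell adjusted over the list alone). Their relative median was -1.14 (camera, adjusted p = 2.36e-07, and adjusted p = 0.00354 with an estimated correlation). Pkhd1, which encodes the ciliary protein fibrocystin, fell from 55.0 to 6.38 TPM (-3.51 ± 0.71) and the mucin Muc1 from 752 to 202 TPM (-2.06 ± 0.38). The ductal keratin Krt19 fell (-1.55 ± 0.47, adjusted p = 0.0251), with 1884 TPM in 12 h library 1 against 407 to 429 in the other 3 libraries. That call was lost without 0 h library 2 (-1.42, adjusted p = 0.0772), 0 h library 3 (-1.52, adjusted p = 0.0837), 12 h library 2 (-1.14, adjusted p = 0.0891) or 12 h library 4 (-1.52, adjusted p = 0.0515). Epcam itself, the sorting marker, and the ductal transcription factor gene Sox9 were not called (-0.14 ± 0.15, adjusted p = 0.564, and -0.10 ± 0.22, adjusted p = 0.798), with Sox9 at 222 TPM in 12 h library 1 and 337 to 360.2 in the other 3. Of the 24 cholesterol biosynthesis genes, 0 rose, 11 fell and 13 were not called (0 and 14 rose and fell adjusted over the list alone, camera, adjusted p = 1.5e-09, and adjusted p = 0.0684 with an estimated correlation). Among them Cyp51 (-1.85 ± 0.31) and Insig1 (-1.70 ± 0.25) fell. Of 20 genes of the fetal-like and regenerative list, 2 rose, 5 fell and 13 were not called (5 and 6 rose and fell adjusted over the list alone, camera, adjusted p = 0.0241, and adjusted p = 0.108 with an estimated correlation).

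Some hepatocyte and macrophage transcripts were also lower. Albumin (Alb), made by hepatocytes, fell from 863 to 65.2 TPM (-4.23 ± 0.48), and Serpina1a by a like amount (-4.27 ± 0.67). Of 17 hepatocyte markers, 0 rose, 13 fell and 4 were not called (0 and 16 rose and fell adjusted over the list alone). Their relative median was -3.00 (camera, adjusted p = 2.03e-11, and adjusted p = 0.0684 with an estimated correlation). Macrophage markers Cd14 (-2.89 ± 0.25) and Csf1r (-2.80 ± 0.47) fell, 3 of 6 such markers in all and 3 adjusted over the list alone (camera, adjusted p = 0.00267, and adjusted p = 0.0684 with an estimated correlation). Of 7 endothelial, 7 stellate and 7 erythroid markers limma called 0, also over each list alone, and camera called none of these lists (adjusted p = 0.528, 0.413 and 0.0701). The largest rises included the bicarbonate transporter family gene Slc4a11 (from 4.11 to 105 TPM, 4.87 ± 0.46), Tnfrsf22 (4.45 ± 0.28) and Rangrf (4.47 ± 0.47). The largest falls included Ptgds (-5.16 ± 0.77), at 6.00 TPM in 12 h library 4 and 0 to 0.271 in the other 3, and the keratin Krt23 (-4.62 ± 0.64). Among 25 p53 targets Pidd1 (3.17 ± 0.55) and Phlda3 (2.72 ± 0.43) rose and the death receptor gene Fas (-4.32 ± 0.80) fell. Among 22 YAP/TAZ targets Ctgf (2.67 ± 0.28) rose and Ankrd1 (-2.30 ± 0.35) fell. Igfbp3 (3.49 ± 0.54) and the glycolytic gene Pkm (1.49 ± 0.17, at 424 TPM in 12 h library 1 and 248 to 269 in the others) rose. Il1rn (-2.43 ± 0.24) fell. In all, 3037 of 13286 genes were called, 2077 higher and 960 lower, and 1184 higher and 1394 lower with TMM-like scaling. That scaling moved the median log2 change of all genes from 0.27 to 0.02, so list medians are given relative to all genes.

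By 24 h, replication genes had risen. Rfc3, of the clamp loader, rose by 3.76 ± 0.58 in log2 terms (SE, n = 3 per group), the uracil-DNA glycosylase gene Ung by 3.38 ± 0.52 and the chromatin assembly factor gene Chaf1b by 2.90 ± 0.52. Of 27 S phase and replication genes, 14 rose, 0 fell and 13 were not called (16 and 0 rose and fell adjusted over the list alone). Their relative median was 1.53 (camera, adjusted p = 1.57e-05, and adjusted p = 0.0307 with an estimated correlation). The G2/M genes were not called as a group, with 5 of 28 higher, 0 lower and the same counts adjusted over the list alone (camera, adjusted p = 0.356). Cdk1, the kinase that drives entry into mitosis, rose from 3.60 to 29.7 TPM (3.21 ± 0.45). Uhrf1, which recruits DNMT1 to replicating DNA, rose from 3.01 to 19.1 TPM (2.88 ± 0.59) and Dnmt1, the maintenance DNA methyltransferase gene, from 4.24 to 19.3 TPM (1.76 ± 0.45). Tet1, whose product oxidises 5mC to 5hmC, rose from 0.0909 to 6.47 TPM (2.34 ± 0.62, adjusted p = 0.0118). Its 24 h libraries 1 to 3 held 14.4, 1.53 and 3.43 TPM, and without library 1, which had few genes, the call was lost (1.26 ± 0.54, adjusted p = 0.113).

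Inflammatory and immediate-early transcripts were also lower than at 0 h after 24 h. Of 27 inflammation and NF-kB genes, 0 rose, 21 fell and 6 were not called (0 and 21 rose and fell adjusted over the list alone). The list lay -2.55 from all genes (camera, adjusted p = 2.95e-16, and adjusted p = 0.0254 with an estimated correlation). Cxcl10 (-4.98 ± 0.67) and the NF-kB feedback gene Tnfaip3 (-4.09 ± 0.58) fell, and Ccl20 went from 116 TPM to 0 in each 24 h library. Of 30 immediate-early genes, 0 rose, 20 fell and 10 were not called (0 and 21 rose and fell adjusted over the list alone, camera, adjusted p = 5.89e-12, and adjusted p = 0.134 with an estimated correlation). Fos (-5.12 ± 0.65) and Fosb (-4.75 ± 0.71) were among the falls. Of 25 ductal genes, 3 rose, 12 fell and 10 were not called (4 and 14 rose and fell adjusted over the list alone, camera, adjusted p = 1.57e-05, and adjusted p = 0.0118 with an estimated correlation). Falls included those of the claudin gene Cldn4 (from 3189.6 to 647 TPM, -2.23 ± 0.24) and of Krt19 (-2.18 ± 0.51). The Krt19 call was lost without 24 h library 1 (-1.44, adjusted p = 0.0522). The ErbB and MAPK list was lower too, with 2 rises and 6 falls among 23 genes, 2 and 7 adjusted over the list alone (camera, adjusted p = 0.00967, and adjusted p = 0.217 with an estimated correlation). So were cholesterol biosynthesis, with 3 and 7 of 24, 4 and 10 over the list alone (adjusted p = 0.00921, and adjusted p = 0.393 with an estimated correlation), and the interferon list, with 0 and 3 of 22, 0 and 3 over the list alone (adjusted p = 0.0331, and adjusted p = 0.217 with an estimated correlation).

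Some hepatocyte, macrophage and erythroid markers were lower than at 0 h at 24 h as well. Of 17 hepatocyte markers 0 rose, 9 fell and 8 were not called (0 and 10 rose and fell adjusted over the list alone, camera, adjusted p = 1.01e-05, and adjusted p = 0.217 with an estimated correlation). Alb stood at -4.57 ± 0.52. Macrophage markers had 0 rises and 3 falls among 6, 0 and 4 adjusted over the list alone (camera, adjusted p = 0.000855, and adjusted p = 0.0549 with an estimated correlation). Csf1r stood at -3.81 ± 0.51. Erythroid markers had 0 and 4 among 7, 0 and 5 over the list alone (camera, adjusted p = 0.00758, and adjusted p = 0.217 with an estimated correlation), Hbb-bt at -3.91 ± 0.99. The endothelial and stellate lists were not called (camera, adjusted p = 0.761 for both), with 0 of 7 markers called in each by limma, also over the list alone. The liver carboxylesterase gene Ces1d fell from 654 to 9.67 TPM (-7.08 ± 0.62) and the involucrin gene Ivl (-6.73 ± 0.76). Slc4a11 (5.62 ± 0.50) and the cadherin gene Cdh17 (from 0.224 to 27.3 TPM, 4.56 ± 0.58) rose. The p53 target Ccng1 rose (2.90 ± 0.47) and Gdf15 fell (-4.88 ± 0.85). F3, which encodes tissue factor, fell (-2.88 ± 0.28). Pkm (2.27 ± 0.18) and Igfbp3 (4.04 ± 0.59) rose. At 24 h 3277 genes were called, 2064 higher and 1213 lower (1280 and 1678 with TMM-like scaling, which moved the median of all genes from 0.15 to -0.09).

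At 48 h the cells expressed the mitotic genes. Each of the 28 G2/M genes rose (28 and 0 adjusted over the list alone), with a relative median of 4.19 (camera, adjusted p = 1.25e-20, and adjusted p = 0.00694 with an estimated correlation). Cdk1 rose from 3.60 to 286 TPM (6.37 ± 0.45, SE, n = 3 per group), the proliferation marker Mki67 from 0.269 to 21.7 TPM (4.06 ± 0.50), and Ube2c (6.21 ± 0.81), Ccnb1 (5.89 ± 0.72) and Plk1 (5.87 ± 0.56) by comparable amounts. Of 27 S phase genes, 24 rose, 0 fell and 3 were not called (25 and 0 rose and fell adjusted over the list alone). The list lay 3.10 above all genes (camera, adjusted p = 4.23e-13, and adjusted p = 0.00295 with an estimated correlation). The ribonucleotide reductase genes Rrm2 (5.94 ± 0.67) and Rrm1 (4.45 ± 0.62) and the transcription factor gene E2f1 (4.50 ± 0.81) were among them. Uhrf1 (from 3.01 to 69.5 TPM, 4.62 ± 0.59) and Dnmt1 (from 4.24 to 29.1 TPM, 2.32 ± 0.45) rose with them, as did the Polycomb gene Ezh2.

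Immediate-early genes reached lower levels at 48 h than at 0 h. Of 30, 0 rose, 24 fell and 6 were not called (0 and 26 rose and fell adjusted over the list alone, camera, adjusted p = 2.2e-22, and adjusted p = 0.0304 with an estimated correlation). Atf3 fell from 664 to 6.30 TPM (-6.82 ± 0.57) and the phosphatase gene Dusp1 by a log2 change of -5.17 ± 0.55. Fosb was listed at 0 in each 48 h library against 57.5 TPM at 0 h. Of 27 inflammation genes, 2 rose, 16 fell and 9 were not called (2 and 17 rose and fell adjusted over the list alone, camera, adjusted p = 3.89e-10, and adjusted p = 0.0507 with an estimated correlation). Cxcl10 (-6.05 ± 0.67) fell, as did Lif (-5.20 ± 0.61), and the acute-phase gene Saa3 rose (4.66 ± 0.71). Of 25 ductal genes, 4 rose, 12 fell and 9 were not called (4 and 12 rose and fell adjusted over the list alone, camera, adjusted p = 4.34e-06, and adjusted p = 0.00400 with an estimated correlation). Cldn4 stood at -4.12 ± 0.24, Epcam at -1.25 ± 0.16 and Sox9 at -1.32 ± 0.23. The interferon list had 1 rise and 7 falls among 22, the same adjusted over the list alone (camera, adjusted p = 0.00531, and adjusted p = 0.112 with an estimated correlation). Ifit3 stood at -4.11 ± 0.68. ErbB and MAPK genes had 1 and 6 among 23, the same over the list alone (adjusted p = 0.0178, and adjusted p = 0.261 with an estimated correlation), and ribosome biogenesis 4 and 6 among 29, 4 and 8 over the list alone (adjusted p = 0.0218, and adjusted p = 0.483 with an estimated correlation).

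Other genes went both ways at 48 h. Mesothelin (Msln) rose from 23.8 to 257 TPM (3.66 ± 0.29), Pkm from 107 to 1039 TPM (3.37 ± 0.18), Cdh17 from 0.224 to 79.6 TPM (6.20 ± 0.58) and the receptor tyrosine kinase gene Axl by a log2 change of 5.54 ± 0.64. The cell cycle inhibitor gene Cdkn1a fell from 1094 to 93.9 TPM (-3.73 ± 0.32), the keratinocyte envelope gene Sprr1a from 8834 to 160.2 TPM (-6.14 ± 0.39), and Gdf15 (-5.91 ± 0.85), Gadd45a (-3.42 ± 0.32), F3 (-4.68 ± 0.28) and Ces1d (-7.05 ± 0.62) were lower. Of 17 hepatocyte markers, 2 rose, 7 fell and 8 were not called (2 and 9 rose and fell adjusted over the list alone, camera, adjusted p = 0.00634, and adjusted p = 0.483 with an estimated correlation). Alb (-2.93 ± 0.52) and Serpina1c (-4.74 ± 0.86) fell. The fibrinogen gene Fgb rose from 10.3 to 163 TPM (3.31 ± 0.90), a call lost without 0 h library 3 (2.45, adjusted p = 0.107). Erythroid markers had 0 rises and 4 falls among 7, the same adjusted over the list alone (camera, adjusted p = 0.00305, and adjusted p = 0.227 with an estimated correlation), Hba-a2 at -7.07 ± 1.14. At 48 h 3486 genes were called, 2329 higher and 1157 lower (1749 and 1519 with TMM-like scaling, which moved the median of all genes from 0.26 to 0.08).

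Organoids at 6 days kept high cell cycle transcripts, and some WNT target and stem cell genes were higher than at 0 h. Lgr5, a gene that marks dividing epithelial stem cells, rose from 0.833 to 13.3 TPM (3.04 ± 0.67, SE, n = 3 per group, adjusted p = 0.00290), and the WNT targets Axin2 (4.03 ± 0.90) and Sp5 (4.35 ± 0.65) rose. Of 14 WNT targets and LGR5 stem-cell genes, 8 rose, 1 fell and 5 were not called (8 and 1 rose and fell adjusted over the list alone). As a group they were not called (camera, adjusted p = 0.0655, and 0.0469 with TMM-like scaling). Each of the 28 G2/M genes rose, 28 adjusted over the list alone, and 24 of 27 S phase genes, 24 over the list alone, with 0 falls in either (camera, adjusted p = 2.06e-19 and 9.42e-10, and adjusted p = 0.00819 for both with an estimated correlation). Cdk1 reached 282 TPM (6.42 ± 0.45), Ube2c 339.8 (6.65 ± 0.81), Mki67 15.4 (3.46 ± 0.50) and Rrm2 rose by a log2 change of 5.55 ± 0.67. Of 20 fetal-like and regenerative genes, 10 rose, 7 fell and 3 were not called (10 and 7 rose and fell adjusted over the list alone), and the list was not called (camera, adjusted p = 0.372). Ly6a rose from 195 to 2738 TPM (4.04 ± 0.36) and Msln from 23.8 to 434 TPM (4.49 ± 0.29). Plaur, the urokinase receptor gene, fell from 3469 to 280.5 TPM (-3.67 ± 0.22).

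Ductal genes moved apart in organoids. Of 25, 3 rose, 11 fell and 11 were not called (3 and 14 rose and fell adjusted over the list alone, camera, adjusted p = 8.36e-05, and adjusted p = 0.00819 with an estimated correlation). The protease gene Mmp7 rose from 104 to 1892 TPM (5.04 ± 1.14) and the keratin gene Krt7 from 155 to 796 TPM (2.64 ± 0.25). The chloride channel gene Cftr (-3.35 ± 0.70), Epcam (from 1555 to 1026 TPM, -0.64 ± 0.16) and Sox9 (-1.18 ± 0.23) fell. Of 24 extracellular matrix and integrin genes, 14 rose, 3 fell and 7 were not called (15 and 4 rose and fell adjusted over the list alone), tenascin (Tnc, 2.59 ± 0.60) among the rises, and the list was not called (camera, adjusted p = 0.116). Immediate-early genes had 0 rises and 24 falls among 30, 0 and 25 adjusted over the list alone (camera, adjusted p = 5.55e-18, and adjusted p = 0.0479 with an estimated correlation). Fosl1 went from 1221 to 16.9 TPM (-6.16 ± 0.33), with Atf3 at -6.10 ± 0.57 and the ErbB ligand gene Hbegf at -3.46 ± 0.22. Inflammation genes had 1 and 16 among 27, 2 and 17 over the list alone (adjusted p = 1.28e-10, and adjusted p = 0.0479 with an estimated correlation). Cxcl2 fell from 3535 to 50.5 TPM (-6.48 ± 0.49). ErbB and MAPK genes had 3 and 6 among 23, 3 and 7 over the list alone (adjusted p = 0.00880, and adjusted p = 0.211 with an estimated correlation). Interferon genes had 1 and 9 among 22, 1 and 10 (adjusted p = 0.00294, and adjusted p = 0.0975 with an estimated correlation), Ifit3 at -4.04 ± 0.68. Ribosome biogenesis had 1 and 11 among 29, the same over the list alone (adjusted p = 0.000990, and adjusted p = 0.254 with an estimated correlation), with nucleostemin (Gnl3) at -1.63 ± 0.36. Glycolysis had 9 and 3 among 22, 11 and 3 (adjusted p = 0.0187, and adjusted p = 0.278 with an estimated correlation), Pkm at 3.55 ± 0.18.

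The largest rises outside the lists were those of Cdh17 (6.77 ± 0.58), Slc4a11 (6.73 ± 0.50) and the growth factor binding protein genes Igfbp4 (from 14.4 to 964 TPM, 6.14 ± 0.46) and Igfbp3 (5.48 ± 0.59). The largest falls included Ces1d (from 654 to 0.701 TPM, -9.07 ± 0.62) and Fxyd1 (-7.66 ± 0.83). The p53 targets Ccng1 (4.52 ± 0.47) and Phlda3 (4.06 ± 0.46) rose and Gdf15 (-4.05 ± 0.85) fell, as did the imprinted growth gene Grb10 (-3.49 ± 0.38) and the pericyte gene Rgs5 (-3.88 ± 0.51). Of 17 hepatocyte markers, 1 rose, 10 fell and 6 were not called (2 and 10 rose and fell adjusted over the list alone, camera, adjusted p = 0.000744, and adjusted p = 0.254 with an estimated correlation), Alb at -5.00 ± 0.52 and Serpina1c at -6.07 ± 0.86. Macrophage markers had 0 rises and 2 falls among 6, the same adjusted over the list alone (camera, adjusted p = 0.0278, and adjusted p = 0.199 with an estimated correlation). Erythroid markers had 0 and 4 among 7, the same (adjusted p = 0.00245, and adjusted p = 0.202 with an estimated correlation), with Hba-a2 listed at 0 in each organoid library. In organoids 3888 genes were called, 2432 higher and 1456 lower (2126 and 1768 with TMM-like scaling, which moved the median of all genes from 0.18 to 0.07, and 2257 and 1961 with quantile normalization).

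Organoids differed from cells at 48 h in 85 called genes, 57 higher and 28 lower. The balance was not stable, with 20 higher and 23 lower at a pseudocount of 0.1, 71 and 92 in the second of 2 sets of table columns alone, and 16 and 23, 15 and 17, and 10 and 15 without organoid libraries 1, 2 and 3. Cdkn1a, the p53-induced inhibitor of the cell cycle, rose from 93.9 to 304 TPM (1.70 ± 0.31, SE, n = 3 per group). Of 25 p53 targets, 1 rose, 0 fell and 24 were not called (13 and 0 rose and fell adjusted over the list alone). The list lay 1.17 above all genes (camera, adjusted p = 5.04e-16, and adjusted p = 0.0171 with an estimated correlation). Of 24 extracellular matrix and integrin genes, 3 rose, 1 fell and 20 were not called (7 and 1 rose and fell adjusted over the list alone, camera, adjusted p = 2.24e-07, and adjusted p = 0.0106 with an estimated correlation). The laminin gene Lamb3 (1.98 ± 0.42) and fibronectin (Fn1, 1.88 ± 0.37) were higher and Plaur (-1.20 ± 0.21) lower. The fetal-like list was higher, with 1 rise (Ly6a, 1.99 ± 0.35) and 1 fall (Plaur) among 20, 9 and 3 adjusted over the list alone (camera, adjusted p = 9.4e-06, and adjusted p = 0.0106 with an estimated correlation). Of 14 WNT and stem-cell genes 2 rose, Cd44 (1.12 ± 0.23) and Ccnd1 (0.86 ± 0.18), with 2 over the list alone and 0 falls in either (camera, adjusted p = 0.000579, and adjusted p = 0.0623 with an estimated correlation). Lgr5 itself was not called (1.80 ± 0.66, adjusted p = 0.374). Of 25 ductal genes 3 rose and 0 fell, 7 and 1 over the list alone (camera, adjusted p = 0.0116, and adjusted p = 0.0531 with an estimated correlation), namely Cldn4 (from 178 to 522 TPM, 1.59 ± 0.23), Krt7 (1.33 ± 0.24) and Krt8 (0.88 ± 0.18).

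Stra6, which encodes a retinol transporter, rose between 48 h and organoids (4.53 ± 0.61), with Il18r1 (3.34 ± 0.52). Gckr (-3.91 ± 0.60), Fgfr3 (-3.63 ± 0.51), Dab1 (-3.35 ± 0.51), Nrn1 (-3.14 ± 0.41), Rgs5 (-2.87 ± 0.50) and the iron-binding gene Lcn2 (-1.07 ± 0.14) fell. Hepatocyte markers were lower as a group, with 0 called among 17 and 1 rise and 1 fall over the list alone (camera, adjusted p = 0.0116, and adjusted p = 0.546 with an estimated correlation), Alb at -2.07 ± 0.51 (adjusted p = 0.0906). The S phase list (adjusted p = 0.0152, and adjusted p = 0.181 with an estimated correlation) and ribosome biogenesis (adjusted p = 0.0164, and adjusted p = 0.546 with an estimated correlation) were lower with 0 members called by limma over all genes or over the list alone. At an unadjusted p under 0.05 limma counted 1061 genes in this comparison. The count of 85 fell to 54, 25 and 34 without 48 h libraries 1, 2 and 3 and to 39, 32 and 25 without organoid libraries 1, 2 and 3. The naming rule gives 30 called genes here, of which 18, 11, 9, 15, 13 and 12 kept their call in those fits and 8 in all 6, Cldn4, Lcn2, Stra6, Il18r1, Fgfr3, Dab1, Gckr and Nrn1.

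**Figure D1:**
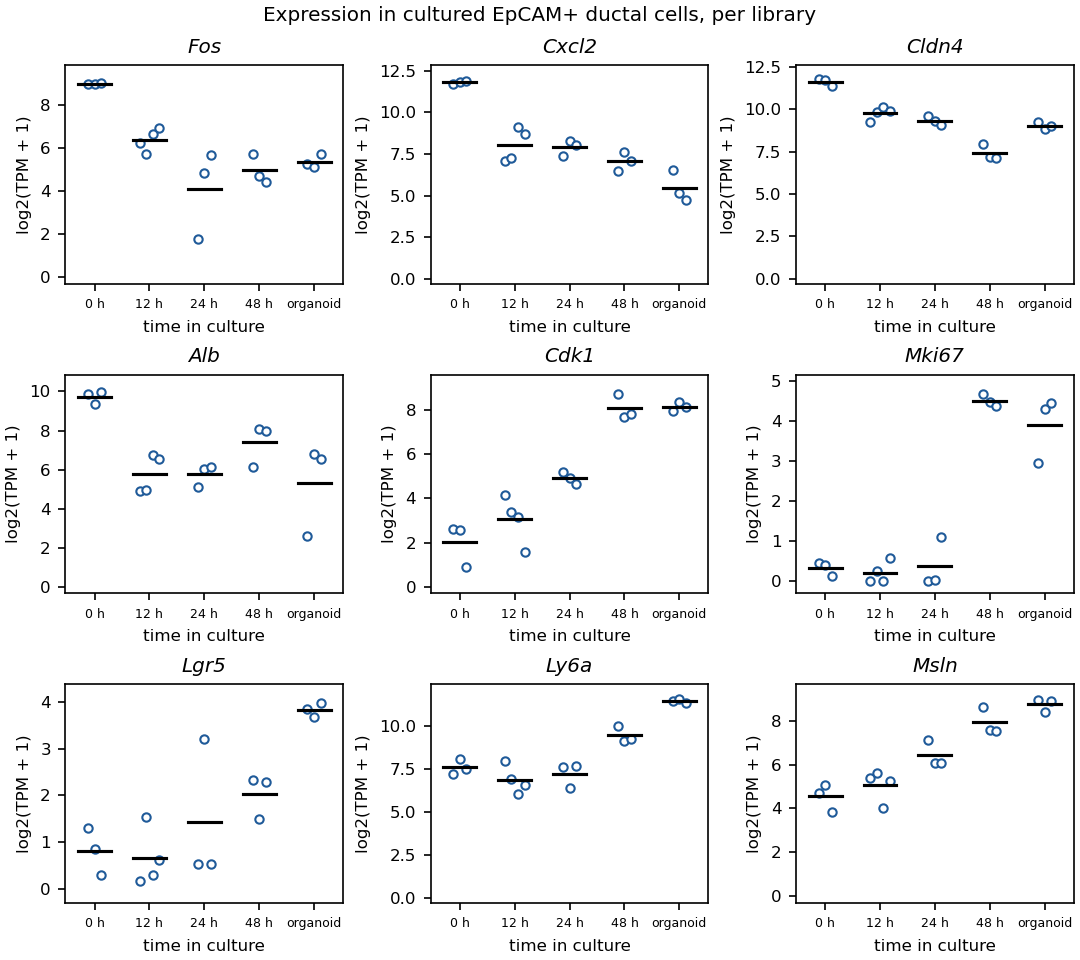
TPM as log2(TPM + 1) of 9 genes in the 16 culture libraries at 0, 12, 24 and 48 h and in organoids. Points are libraries and bars their means. Fos, Cxcl2, Cldn4 and Alb fell and Cdk1, Mki67, Lgr5, Ly6a and Msln rose in organoids against 0 h.

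Changes against 0 h were alike across culture times. Across 13286 genes, which are not independent replicates, the log2 changes of 2 times had Spearman correlations of 0.671 (12 h and organoids) to 0.887 (48 h and organoids), against 0.487 to 0.507 in 50 simulations of unchanged groups that share the 0 h libraries. The covariance was 1.07 to 1.72 against 0.190 to 0.199 simulated. From 48 h to organoids, 1882 genes rose at both times (426.3 for independent lists) and 954 fell at both (127). Part of the excess can come from the shared 0 h libraries, which were not divided between the times compared.

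In the animal, some matrix genes and the protease gene Mmp7 were higher after 3 days of DDC in the sorted cells, in which 1 of 16 stellate cell markers, Rgs5, was higher as well, and few cell cycle genes were called. Mmp7 rose from 8.16 to 265 TPM (4.98 ± 0.70, SE, n = 2 per group) and the metalloprotease inhibitor gene Timp1 (2.87 ± 0.26), the integrin gene Itga2 (2.38 ± 0.36) and the basement membrane collagen gene Col4a1 (1.71 ± 0.19) rose. Of 25 extracellular matrix and integrin genes, 6 rose, 0 fell and 19 were not called (18 and 0 rose and fell adjusted over the list alone). The list lay 0.71 above all genes (camera, adjusted p = 7.13e-11, and adjusted p = 0.160 with an estimated correlation). Of 28 G2/M genes, 1 rose, 0 fell and 27 were not called (10 and 0 rose and fell adjusted over the list alone), the 1 being Top2a (2.53 ± 0.40). Their relative median was 1.51 (camera, adjusted p = 7.13e-11, and adjusted p = 0.578 with an estimated correlation). Of 27 S phase genes 0 were called by limma, 6 rising and 0 falling adjusted over the list alone (camera, adjusted p = 1.58e-05, and adjusted p = 0.577 with an estimated correlation). Mki67 averaged 29.1 TPM against 3.05 without damage (2.65 ± 0.51, adjusted p = 0.0583), short of a call. Uhrf1 rose (2.11 ± 0.37). Of 20 fetal-like genes, 4 rose, 0 fell and 16 were not called (4 and 0 rose and fell adjusted over the list alone, camera, adjusted p = 0.00232, and adjusted p = 0.578 with an estimated correlation). Il1rn, which encodes the interleukin-1 receptor antagonist, rose from 148 to 1803 TPM (3.54 ± 0.31), with S100a6 (2.84 ± 0.44), Anxa3 (1.16 ± 0.16), Cd44 (1.49 ± 0.22) and the YAP target Ctgf (3.20 ± 0.50).

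Few interferon and immediate-early genes were called as lower at day 3. Of 22 interferon genes, 0 rose, 1 fell and 21 were not called (0 and 7 rose and fell adjusted over the list alone, camera, adjusted p = 7.62e-07, and adjusted p = 0.160 with an estimated correlation), the 1 being Ifit3 (-2.82 ± 0.24). Of 30 immediate-early genes, 0 rose, 2 fell and 28 were not called (2 and 12 rose and fell adjusted over the list alone, camera, adjusted p = 0.000245, and adjusted p = 0.160 with an estimated correlation), namely Fosb (-1.29 ± 0.21) and Gadd45b (-1.30 ± 0.22). Ribosome biogenesis had 0 of 29 called by limma over all genes or the list alone (camera, adjusted p = 0.000654, and adjusted p = 0.578 with an estimated correlation). Pkhd1 (-1.11 ± 0.17), the immunoglobulin receptor gene Pigr (-2.76 ± 0.30), vitronectin (Vtn, -3.07 ± 0.29), Ces1c (-4.47 ± 0.71) and Ces1d (-2.68 ± 0.24) fell. Serpina3n (3.88 ± 0.59) and Srd5a2 (3.85 ± 0.37) rose. Alb fell from 3832 to 1335 TPM (-1.52 ± 0.17), with 0 rises and 1 fall among 24 hepatocyte markers, 1 and 5 adjusted over the list alone, and the list was not called (camera, adjusted p = 0.0747). Stellate cell markers had 1 rise (Rgs5, from 36.4 to 630.1 TPM, 4.12 ± 0.31) and 0 falls among 16, the same over the list alone (camera, adjusted p = 0.000745, and adjusted p = 0.578 with an estimated correlation). The macrophage gene Lyz2 was not called (2.53 ± 0.58, adjusted p = 0.0871).

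At day 3 limma called 156 of 14048 genes, 94 higher and 62 lower, and 2588 had an unadjusted p under 0.05. These calls rest on few libraries, since without undamaged libraries 1 and 2 in turn 3 and 0 genes were called, without day 3 libraries 1 and 2, 34 and 12, and 0 with a limma prior without trend or with no filter on low values. The naming rule fixed before the data gives 37 called genes for day 3, of which 1, 0, 14 and 9 kept their call in those 4 fits and 0 in all of them.

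At day 5 of DDC, 7 of 28 G2/M genes were called as higher. Cdk1 rose from 1.47 to 40.9 TPM (4.07 ± 0.52, SE, n = 2 per group), Mki67 from 3.05 to 42.7 TPM (3.43 ± 0.51), Top2a by a log2 change of 3.30 ± 0.40 and Aurkb of 3.46 ± 0.63. Of the G2/M genes, 7 rose, 0 fell and 21 were not called (23 and 0 rose and fell adjusted over the list alone). Their median log2 change was 2.13 before subtracting that of all genes (camera, adjusted p = 1.25e-14, and adjusted p = 0.499 with an estimated correlation). Of 27 S phase genes, 2 rose, 0 fell and 25 were not called (11 and 0 rose and fell adjusted over the list alone, camera, adjusted p = 1.05e-05, and adjusted p = 0.499 with an estimated correlation), the 2 being Chaf1b and Mcm2 (1.81 ± 0.32). Of 25 extracellular matrix and integrin genes, 8 rose, 0 fell and 17 were not called (17 and 0 rose and fell adjusted over the list alone, camera, adjusted p = 1.21e-11, and adjusted p = 0.121 with an estimated correlation). Against undamaged liver Mmp7 (from 8.16 to 399 TPM, 5.80 ± 0.70), Itga2 (3.06 ± 0.36), Timp1 (2.36 ± 0.26) and the urokinase gene Plau (1.84 ± 0.29) were higher. Of 20 fetal-like genes, 4 rose, 0 fell and 16 were not called (6 and 0 rose and fell adjusted over the list alone, camera, adjusted p = 0.000185, and adjusted p = 0.499 with an estimated correlation). Il1rn reached 2377 TPM (3.97 ± 0.31), S100a6 (2.97 ± 0.44), Cd44 (1.64 ± 0.22) and Ctgf (3.07 ± 0.50) rose. Among 25 ductal genes 3 rose and 1 fell, the same adjusted over the list alone (camera, adjusted p = 0.349), Krt7 (1.36 ± 0.25) and Cldn4 (from 2351 to 4775 TPM, 1.02 ± 0.19) among the rises.

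Of 27 inflammation genes 2 rose at day 5, the monocyte chemokine gene Ccl2 (5.18 ± 0.71) and Csf2, which was listed at 0 in both undamaged libraries, and 0 fell, 3 and 1 adjusted over the list alone (camera, adjusted p = 0.757). Of 30 immediate-early genes, 1 rose, 5 fell and 24 were not called (1 and 14 rose and fell adjusted over the list alone, camera, adjusted p = 6.31e-08, and adjusted p = 0.121 with an estimated correlation). Fosb (-1.93 ± 0.21), Jun (-1.30 ± 0.18) and Egr1 (-1.28 ± 0.18) fell. Of 22 interferon genes, 0 rose, 2 fell and 20 were not called (0 and 5 rose and fell adjusted over the list alone, camera, adjusted p = 1.64e-05, and adjusted p = 0.176 with an estimated correlation), the 2 being Ifit3 (-2.73 ± 0.24) and Irf9 (-1.21 ± 0.24). Ribosome biogenesis had 0 of 29 called by limma over all genes or the list alone (camera, adjusted p = 0.000112, and adjusted p = 0.526 with an estimated correlation). Outside the lists Ly6d (5.93 ± 0.61), Wfdc18 (4.26 ± 0.37) and the histone gene Hist2h3c2 (5.54 ± 0.58) rose, and Ces1c (-4.82 ± 0.71), Vtn (-3.13 ± 0.29) and Pigr (-2.89 ± 0.30) fell. Hepatocyte markers were lower, with 1 rise and 2 falls among 24, 2 and 6 adjusted over the list alone (camera, adjusted p = 0.0206, and adjusted p = 0.526 with an estimated correlation). Alb fell from 3832 to 1095 TPM (-1.81 ± 0.17) and Cyp2e1 too (-3.13 ± 0.60), and Mup20, listed at 0 in both undamaged libraries, was the rise. Endothelial markers were lower with 0 of 20 called, 0 rises and 1 fall over the list alone (camera, adjusted p = 0.000292, and adjusted p = 0.526 with an estimated correlation). Erythroid markers were lower with 0 of 8 called, 0 and 6 over the list alone (adjusted p = 0.000245, and adjusted p = 0.499 with an estimated correlation). Rgs5 was higher (3.42 ± 0.31), as 1 of 16 stellate markers, 2 over the list alone, and Lyz2 was not called (2.86 ± 0.58, adjusted p = 0.0508).

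At day 5 limma called 331 genes, 220 higher and 111 lower, with 2900 at an unadjusted p under 0.05. Without undamaged libraries 1 and 2 in turn 0 and 39 were called, without day 5 libraries 1 and 2, 27 and 6, and 0 with a limma prior without trend or with no filter on low values. The naming rule gives 54 called genes for day 5, of which 0, 11, 10 and 4 kept their call in those 4 fits and 0 in all of them. Day 3 and day 5 shared 82 rises (1.47 for independent lists) and 47 falls (0.490), with a Spearman correlation of 0.779 across genes against 0.456 simulated for unchanged groups, and a covariance of 0.399 against 0.110. Part of that excess can come from the 2 shared undamaged libraries, which were not divided between the days.

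Between day 3 and day 5, limma called 0 genes (smallest adjusted p = 0.264), with 549 at an unadjusted p under 0.05. Pcgf1, of the Polycomb list, had the value 1.53 ± 0.37 (SE, n = 2 per group, adjusted p = 0.978), Cdk1 1.21 ± 0.52, Ccl2 1.65 ± 0.71 and the shear-responsive gene Klf2 -1.27 ± 0.32 (limma, adjusted p = 1 for each). As groups, G2/M genes lay higher at day 5 (relative median 0.67, camera, adjusted p = 8.21e-05, and adjusted p = 0.795 with an estimated correlation) and immediate-early genes lower (-0.18, adjusted p = 0.000625, and adjusted p = 0.521 with an estimated correlation). Also lower were endothelial (-0.37, adjusted p = 0.000625, and adjusted p = 0.795 with an estimated correlation), stellate (-0.30, adjusted p = 0.0156, and adjusted p = 0.803 with an estimated correlation) and erythroid markers (-1.03, adjusted p = 0.000625, and adjusted p = 0.795 with an estimated correlation). Members called in any of the 25 lists numbered 0, also adjusted over each list alone. Leaving out day 3 libraries 1 and 2 gave 0 and 0 called genes and leaving out day 5 libraries 1 and 2 gave 1 and 2.

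**Figure D2:**
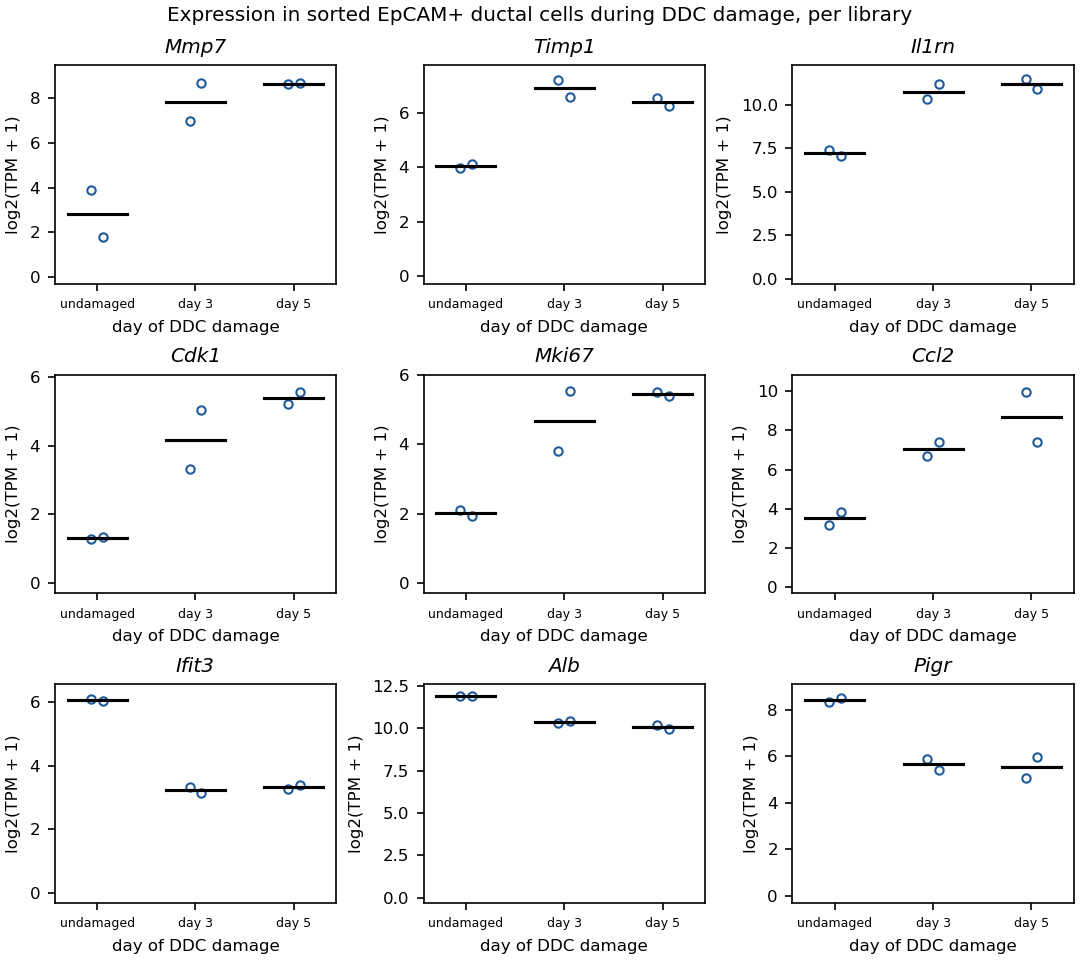
TPM as log2(TPM + 1) of 9 genes in the 6 liver libraries, undamaged and after 3 and 5 days of DDC. Points are libraries and bars their means. Mmp7, Il1rn and Cdk1 lay above the undamaged libraries at day 5, and Alb, Pigr and Ifit3 below.

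Organoid culture and DDC damage were compared across 12616 genes tested in both tables, which share no libraries and were normalised separately. The log2 changes of organoids against 0 h and of day 5 against undamaged liver had a Spearman correlation of 0.435. In both, 104 genes rose (40.0 for independent lists) and 75 fell (12.2), while 19 fell in organoids and rose after damage and 2 did the opposite. Cdk1, Mki67, Uhrf1 and Mmp7 were among those that rose in both and Alb and Ifit3 among those that fell in both. Il1rn (-2.30 in organoids and 3.97 at day 5), Rgs5 (-3.88 and 3.42) and Cldn4 (-2.53 and 1.02) fell in organoids and rose after damage.

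Genes that write, maintain or oxidise DNA methylation did not move as one group. Of 19 such genes, 3, 4, 6 and 4 rose and 0, 1, 3 and 4 fell at 12 h, 24 h, 48 h and in organoids (0, 4, 7 and 4 rises and 0, 1, 3 and 5 falls adjusted over the list alone), and camera called the list at none of these times (adjusted p = 0.577, 0.808, 0.913 and 0.710). At 48 h its median lay 0.12 above that of all genes while the test pointed down. In organoids Uhrf1 (from 3.01 to 49.7 TPM, 4.21 ± 0.59) and Dnmt1 (1.86 ± 0.45) rose. Tet3 fell from 18.9 to 5.48 TPM (-1.84 ± 0.54, adjusted p = 0.0174). The Tet3 call was lost without 0 h library 1 (-1.68, adjusted p = 0.0594), 0 h library 3 (-1.76, adjusted p = 0.0677) or organoid library 3 (-1.71, adjusted p = 0.0591). Tet2 was not called (-1.76 ± 0.66, adjusted p = 0.0562), nor was Tet1 (0.71 ± 0.62, adjusted p = 0.421). At day 5 of DDC Uhrf1 rose from 6.43 to 48.3 TPM (2.71 ± 0.37) and Idh1, whose product makes the cofactor of TET enzymes, from 33.4 to 99.9 TPM (1.57 ± 0.21). Dnmt1 (1.42 ± 0.29, adjusted p = 0.0520), Tet1 (-0.05 ± 0.43, adjusted p = 0.962), Tet2 (-0.58 ± 0.24, adjusted p = 0.219) and Tet3 (-0.12 ± 0.23, adjusted p = 0.809) were not called. Of the 19 genes 2 rose and 1 fell at day 5, 4 and 1 over the list alone (camera, adjusted p = 0.526), the median lying -0.08 from all genes and the test pointing up.

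5hmC was mapped as the set of CCGG sites with at least 1 read, since the files list detected sites and not read numbers. The 6 libraries held 373479 and 442591 (undamaged), 405967 and 438226 (day 3) and 430340 and 469133 (day 5) sites, 648483 in any library and 262608 (40.5%) in all 6. Of these sites, 16.8 and 23.1% lay in the H3K4me3 peaks of organoids in undamaged liver, 22.4 and 22.7% at day 3 and 16.4 and 21.5% at day 5. TET1 peaks held 3.17 and 4.05, 3.91 and 3.97, and 3.05 and 3.83%, promoters 14.6 and 19.4, 18.9 and 19.1, and 14.3 and 18.2%, and gene spans 58.6 and 60.6, 60.1 and 60.5, and 58.2 and 59.9%. Of the sites, 0.659 to 0.682 were shared within groups and 0.630 to 0.737 between them (Jaccard index). Sites in both libraries of 1 group and neither of the other numbered 17527 for day 3 against undamaged, below the 23548 to 31116 of the 2 other splits of those 4 libraries, 28403 for day 5 (17304 to 46632), and 29756 for day 5 against day 3, above its other splits (26515 to 28009). In each comparison 1 of the 2 other splits sets the libraries numbered 1 against those numbered 2. Libraries with the same number deviated together, so these ranges do not show what chance alone would give.

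By detected sites, edgeR called 0 of 7213 promoters at day 3 or day 5 against undamaged liver or between the days. Of these, 122, 85 and 192 had an unadjusted p under 0.05. DESeq2 (0 unadjusted) and limma (64, 37 and 114) called 0 too. Of 8633 H3K4me3 and TET1 peaks edgeR called 0 (106, 90 and 184 unadjusted), or 8 between the days with library number as a block. Of 12795 gene spans it called 0 (261, 288 and 577 unadjusted). These unadjusted counts are below the share of 0.05 that chance gives, and detection carries no level, so 0 calls do not show unchanged 5hmC. The lowest p at day 3 was that of Twsg1, with 12 and 14 sites against 3 and 9 (log2 change 0.93, edgeR adjusted p = 0.993), and at day 5 that of Ykt6, with 5 and 6 against 8 and 11 (-0.84, adjusted p = 0.998). The Tet2 promoter had 4 and 11 detected sites without damage, 9 and 12 at day 3 and 10 and 11 at day 5, that of Lgr5 14 and 18, 15 and 18, and 11 and 20, and that of Epcam 6 and 9, 8 and 8, and 6 and 8. Without undamaged library 2 edgeR called some promoters and peaks at both days. In simulated data 34.1% of 300 planted promoter changes, of unstated size, were recovered, so power is unknown.

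Modified cytosine stood at 78.8% of calls in undamaged liver, 79.4% at day 3 and 78.8% at day 5 over 9689862 CpGs covered at least 5 times in each file. Each file merges both samples of a group, so there are no replicates and no test between groups, and the 95% Wilson intervals given cover counting error only. In H3K4me3 peaks the level was 24.2, 25.2 and 22.9%, but 41.99, 43.6 and 39.2% over CpGs covered at least 10 times. As the mean of per-CpG fractions it was 14.9, 15.2 and 14.8%. So it depends on coverage, and CpGs with many calls raise it and its day 5 drop. The cause was not tested. In promoters it was 41.0, 41.1 and 40.3% and in TET1 peaks 36.4, 36.5 and 35.1%. These levels depend on coverage too. Over CpGs covered at least 1 time promoters had 26.5, 27.1 and 24.8%, and over those covered at least 10 times 50.95, 51.5 and 50.6%. TET1 peaks had 25.9, 26.2 and 24.2%, and 34.1, 35.4 and 31.7%, in the same order. TET1 peaks inside H3K4me3 peaks had 14.5, 14.2 and 13.7% and those outside 62.4, 62.6 and 61.5%. Over CpGs covered at least 1 time the former had 8.55, 8.66 and 7.87% and the latter 59.1, 59.35 and 57.7%. CCGG sites detected by 5hmC profiling in all 6 libraries had 71.1% modified cytosine in undamaged liver and those detected in no library 81.4%. Detection means at least 1 read with a mapping quality of at least 10. It is not a level of 5hmC, and sites without it are not shown to lack 5hmC. The gap depended on the region, with 76.4 and 82.4% outside peaks and 18.7 and 29.4% in H3K4me3 peaks, where it turned to 9.03 and 8.46% over CpGs covered at least 1 time. Of 9767 promoters, 28, 32 and 32 differed by at least 0.2 between undamaged and day 3, undamaged and day 5, and the 2 days, against 18.4, 17.1 and 17.4 on average (highest 31, 24 and 25) in 20 draws of binomial calls with equal levels. Of 9433 H3K4me3 peaks 97, 85 and 96 did (25.9, 21.3 and 24.2 drawn, highest 34, 28 and 40), of 3410 TET1 peaks 40, 39 and 41 (19.7, 16.2 and 17.7, highest 27, 24 and 22) and of 21537 gene spans 62, 55 and 46 (22.9, 21.6 and 25.4). These draws hold counting error and no spread between animals, so an excess over them does not show an effect of damage.

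Among promoters with at least 100 calls in each file, Zfp521 had the largest drop at day 3. It went from 58.4% (50.7 to 65.7) to 33.8% (26.4 to 42.1), and 45.5% at day 5. St3gal6 went from 49.5% (42.8 to 56.2) to 28.3% and 26.9% (22.0 to 32.4) at day 5. Lrp2 went from 33.6% (25.8 to 42.4) to 55.3% (45.7 to 64.6) at day 3 and 34.1% at day 5. Car9 went from 36.9% (30.9 to 43.5) to 58.0 and 55.2% (47.8 to 62.5). Gigyf2 had the largest rise at day 5, from 43.4% (37.8 to 49.2) to 64.7%. The promoter shared by Armc10 and Fbxl13 had the largest drop, from 50.7% to 26.7%. Picked as extremes, these promoters can show such gaps by selection alone, which the intervals ignore. The Tet2 promoter stood at 7.75, 13.5 and 4.13%, that of Tet3 at 53.1, 39.5 and 43.6%, of Lgr5 at 31.5, 41.5 and 23.8%, of Mki67 at 37.9, 33.7 and 37.5% and of Dnmt3b at 61.0, 63.2 and 64.0%.

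**Figure D3:**
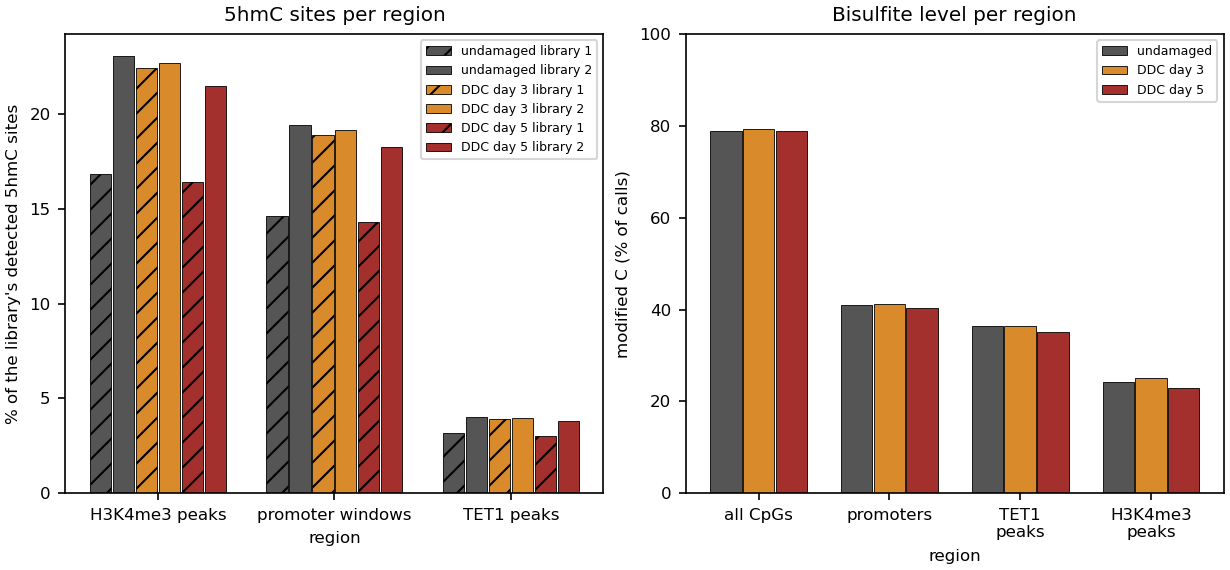
Left, percent of each library's detected 5hmC sites in H3K4me3 peaks, promoters and TET1 peaks (bars are the 6 libraries, hatched for library 1 of each group). Right, modified cytosine as percent of calls by region in the 3 merged files. The H3K4me3 share of 5hmC sites was 16.8 and 16.4% in undamaged library 1 and day 5 library 1 and 21.5 to 23.1% in the other 4.

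In organoids the H3K4me3 list held 15120 peaks (median width 1401.5 bp, 25.6 Mb in all) and the TET1 DamID list 5102 (median 1451 bp, 8.29 Mb), each a single list for its assay. Of the TET1 peaks 2848 (55.8%) overlapped an H3K4me3 peak by at least 1 bp, against 107 (2.11%) on average and 138 at most in 100 random placements on the same chromosomes, a ratio of 26.5. Placed among CCGG sites covered in the bisulfite data, where CpGs are dense, 19.7% overlapped and the ratio was 2.84. H3K4me3 peaks with TET1 were wider (median 2067 bp) than those without (1262 bp), with a median authors' score of 18.7 against 13.1. A TET1 peak lay within 2 kb of an end of 3215 genes and an H3K4me3 peak of 12308, both at the same end of 2986. The widest TET1 peaks lay at the cytoskeletal gene Tpm1 (chromosome 9, 67040948 to 67048612, GRCm38, 7665 bp), Fam83h (6819 bp), the WNT cofactor gene Bcl9l (6599 bp), Cux1 and Sh2b2 (6567 bp). Uhrf1, Lgr5 and Epcam had a TET1 peak at an end, Tet1 and Dnmt1 within their span, and Alb, Krt19, Sox9 and Mki67 none.

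Genes with a TET1 peak at an end made up 22.7% of 13018 genes of the culture table that have a position. They were 56.5% of 23 ErbB and MAPK genes (Egfr, Erbb2, Erbb3 and Hbegf among them), 54.2% of extracellular matrix and integrin genes, 48.0% of p53 targets, 46.7% of immediate-early genes and 44.0% of ductal genes (Epcam, Krt8 and Cdh1 among them). The share was below that of all genes for S phase and inflammation genes (22.2% each), WNT and stem-cell genes (21.4%), DNA methylation genes (21.1%), interferon genes (18.2%), NOTCH genes (15.4%), hepatocyte markers (5.88%, with 35.3% at an H3K4me3 peak) and endothelial, lymphocyte, stellate and erythroid markers (0% each), and 27.3 to 45.5% for the other lists. These shares were not tested. Organoid expression was a median of 22.3 TPM in 2898 genes with both marks, 15.5 TPM in 7947 with H3K4me3 alone, 2.13 TPM in 58 with TET1 alone and 1.49 TPM in 2115 with neither. Genes with a TET1 peak did not move as a group in any of the 8 RNA comparisons (camera, adjusted p = 0.814 to 0.817). At all 4 culture times against 0 h their median turned from above to below that of other genes when peaks anywhere over the gene span were counted. Genes with an H3K4me3 peak lay above other genes at each culture time against 0 h (camera, adjusted p = 0.00114 at each time, and adjusted p = 0.183 with an estimated correlation). The peaks come from organoids, where genes without them had low expression. Such genes that passed the filter through their 0 h values would tend to fall, so the direction may partly follow from how genes were chosen. Across genes, which are not independent replicates, promoter 5hmC and RNA changes had Spearman correlations of -0.0373 at day 3 and 0.0179 at day 5 (6575 genes), and promoter modified cytosine and RNA changes of -0.0104 and -0.0137 (8787 genes).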

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

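Of 35 values tested in the 4 libraries at 12 h by Dixon's ratio, 6 had 1 library far from the others, and about 1 in 20 would by chance. Library 4 had 16186 genes above 0 (14312 to 14516 in the others) and Ptgds at 6.00 TPM (0 to 0.271). Library 1 had Cxcl5 at 333 TPM (70.0 to 112), Krt19 at 1884 (407 to 429), Pkm at 424 (248 to 269) and Sox9 at 222 (337 to 360.2). Between groups, 85 genes differed between organoids and 48 h. Groups of 3 libraries were not screened.

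The numbers of called genes were compared with those from splits of the same libraries, a test chosen after the result was seen. For 12 h, 1 of 35 splits, the real one, called as many as 3037 genes, and the highest other called 673. For 24 h, 48 h, organoids against 0 h and organoids against 48 h, 10 splits are too few for a share under 0.05, with 1 split reaching the real 3277, 3486, 3888 and 85 and the highest other at 7, 4, 0 and 0.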

How the results depend on the processing

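Among called genes named in the text, 0 turned direction under the alternatives run or with 1 library left out. Under the alternatives other than left-out libraries, those at 12 h, 24 h, 48 h and in organoids kept their call in 469 of 479, 400 of 413, 542 of 557 and 619 of 638 values, and those of organoids against 48 h, day 3 and day 5 in 215 of 287, 141 of 207 and 226 of 314. These are genes picked partly for keeping their call. Of all genes the naming rule gives, 58 of 84, 69 of 98, 82 of 105, 86 of 104, 8 of 30, 0 of 37 and 0 of 54 called ones stayed called without any 1 library. Uncalled changes turned sign. Epcam at 12 h ranged from -0.21 to 0.00321 and was 0.00321 without 12 h library 1. Sox9 at 12 h ranged from -0.17 to 0.11 with 1 library left out and was 0.19 in column set 2 alone, 0.03 without 0 h library 1 and 0.11 without 12 h library 1. Tet3 at day 5 ranged from -0.35 to 0.12 and was 0.12 without undamaged library 1, and Tet1 from -0.27 to 0.18, with 0.18 without undamaged library 1 and 0.09 without day 5 library 2 (the cause was not tested).

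In column set 1 alone 1028, 1814, 395 and 312 genes were called at 12 h, 24 h, 48 h and in organoids and 0 between organoids and 48 h. That set holds 1 library each at 24 h, 48 h and in organoids, so these counts assume that the lone library varies like those of the other groups, as do those without 1 liver library. With the column set and sex as covariates 2784, 3043, 3239, 3651 and 63 genes were called in these comparisons. With both doubted libraries left out, a setting chosen after the data had been seen as were those with 1 of them left out, the 24 h count was 1849. The 85 genes of organoids against 48 h became 43 with pseudocount 0.1, 131 with quantile normalization, 36 with eBayes without trend, 38 with no covariate, 163 in column set 2 alone, 129 with the doubted 24 h library left out, 171 with both doubted libraries left out and 503 with only the 2 groups in the fit, and 25 to 54 with 1 library left out (the cause was not tested). At day 3 the count was 0 with no filter on low values, 0 with eBayes without trend, 65 with only the 2 groups in the fit and 0 to 34 with 1 library left out, and at day 5 it was 0, 0 and 0 to 39 for no filter, no trend and left-out libraries. Day 5 against day 3 ranged from 0 to 2 with 1 library left out. With an estimated correlation 2, 3, 4, 5, 3, 0, 0 and 0 lists were called at 12 h, 24 h, 48 h, in organoids, organoids against 48 h, day 3, day 5 and day 5 against day 3, in place of 7, 10, 10, 12, 8, 8, 10 and 5, and 3 to 9 lists for day 5 against day 3 with 1 library left out. With a mean TPM of at least 5 in both tables the correlation of organoid and day 5 changes was 0.476 in place of 0.435.

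A replicate block by column tag, which contains the column set, gave 31 genes for organoids against 48 h, a block by sequencing index gave 70 genes at day 3, and a block by number gave 8 peaks in place of 0 for 5hmC at day 5 against day 3 and changed no other count of promoters or peaks. Neither was shown to pair RNA samples. Correlations below 0.1 were found in 14 of 25 culture pairs with the same column tag (0.00542 to 0.281). They were also found in 4 of 6 liver pairs of the same index block (-0.0349 to 0.105). Pairing by the replicate numbers of the labels was not checked, since the RNA columns do not give them. No paired analysis was possible for modified cytosine because the files merge both samples of a group.

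For 5hmC at day 5 against day 3, 9 peaks were called with only the 2 groups in the fit. With 1 library left out 0 to 16 promoters and 0 to 136 peaks were called at day 3 and 0 to 1 and 0 to 23 at day 5. With all mapping qualities the H3K4me3 shares of sites in undamaged, day 3 and day 5 libraries were 13.9, 15.9 and 13.6%, the TET1 shares 2.45, 2.71 and 2.404% and the promoter shares 11.7, 13.2 and 11.5%. For sites in 2 or more libraries the day 3 shares were 23.1, 4.05 and 19.5%. The planned setting of at least 5 reads per site was not run. With the gene body in place of the promoter, the correlations of 5hmC and RNA changes were -0.0432 at day 3 and -0.00190 at day 5.

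Modified cytosine over all CpGs in the undamaged, day 3 and day 5 files was 79.2, 80.0 and 79.4% at coverage 10, 76.7, 77.4 and 76.3% at coverage 1 and 78.6, 79.1 and 78.6% as the mean of per-CpG fractions, and in H3K4me3 peaks 41.99, 43.6 and 39.2%, 13.5, 14.4 and 12.2%, and 14.9, 15.2 and 14.8%. Promoters differing at day 3, at day 5 and between the days numbered 9, 13 and 19 at coverage 10, 10, 8 and 10 by per-CpG means, and 906, 957 and 921 at a difference of 0.1, with 44 at day 3 and 80 between the days at coverage 1. H3K4me3 peaks differing numbered 6, 4 and 7 at coverage 10, 202, 151 and 206 at coverage 1, and 836, 784 and 834 at a difference of 0.1 (fewer or more CpGs and a lower threshold by construction). The ratio of TET1 and H3K4me3 overlap to placements was 42.5 with at least 50% of the TET1 peak, 33.2 for the 7560 H3K4me3 peaks with the higher scores and 2.84 for placements among CCGG sites, in place of 26.5. Low coverage limits the bisulfite results, and 2 libraries per group those of the liver.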

Other observations

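Some lists were called in few comparisons or none. YAP/TAZ targets had 5, 5, 7 and 7 rises and 4, 4, 5 and 6 falls among 22 genes at 12 h, 24 h, 48 h and in organoids (5, 5, 7 and 7 and 4, 5, 5 and 6 adjusted over the list alone), with F3 lower and Axl higher at 48 h (-4.68 ± 0.28 and 5.54 ± 0.64, SE, n = 3 per group), and were not called (camera, adjusted p = 0.413, 0.939, 0.476 and 0.684). Polycomb, trithorax and NuRD genes had 9, 5, 9 and 8 rises and 2, 3, 3 and 5 falls among 41 (12, 5, 9 and 8 and 2, 3, 3 and 5 over the list alone; camera, adjusted p = 0.413, 0.577, 0.913 and 0.891). The p53 targets had 7, 6, 6 and 9 rises and 5, 8, 8 and 4 falls among 25 (7, 6, 6 and 9 and 5, 9, 11 and 5 over the list alone; camera, adjusted p = 0.678, 0.291, 0.0675 and 0.458). NOTCH genes had 2 rises and 1 fall among 13 in organoids, 2 and 1 over the list alone (camera, adjusted p = 0.716), and imprinting and growth genes 1 and 3 among 11, the same over the list alone (0.159), Grb10 among the falls (-3.49 ± 0.38). Of 10 lymphocyte and neutrophil markers 0 were called by limma at day 3 or day 5, also over the list alone (camera, adjusted p = 0.682 and 0.471).

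Uncalled lists whose median, mean and test differed in sign were, at 12 h, WNT, ErbB and MAPK, ribosome, p53, glycolysis, matrix and endothelial genes, at 24 h matrix genes, at 48 h fetal-like and DNA methylation genes, and in organoids DNA methylation, Polycomb, p53, cholesterol, NOTCH and endothelial genes. Between organoids and 48 h this held for imprinting genes, at day 3 for Polycomb genes, at day 5 for ErbB and MAPK, DNA methylation, Polycomb, NOTCH and inflammation genes, and between the days for YAP/TAZ, DNA methylation and Polycomb genes.

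All tests in this paragraph were chosen after the result was seen, and the first replaced an earlier test whose result had been seen. Hepatocyte transcripts fell at 12 h, Alb by a log2 change of -4.23 ± 0.48. If only less hepatocyte RNA were present, 10 abundant genes should fall alike, and the largest difference between any 2 was 3.53 combined SE (Alb to Hnf4a, bound 3.65), which is more than the 2 that would fit less RNA from hepatocytes and less than the bound that would exclude it, so the test could not tell. TMM-like scaling (-4.56, adjusted p = 3.47e-05) and leaving out both libraries with few genes (-5.04, adjusted p = 7.31e-06) left the fall in place. At day 5 the difference was 6.68 combined SE (Alb to Apob, bound 4.21), so the 10 genes did not fall alike. At both times the bound assumes that all 10 genes are expressed in hepatocytes only, which was not tested. Less RNA from unchanged hepatocytes is therefore not excluded at day 5, and changed hepatocytes or ductal expression remain open as well.

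For the rise of Tet1 at 24 h both tests were chosen after the result was seen. Without the 24 h library with few genes the value was 1.26 ± 0.54 (adjusted p = 0.113) in place of 2.34 ± 0.62, so the call may rest on that library. TMM-like scaling left it at 2.27 (adjusted p = 0.0175). A change in the cells is not ruled out.

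Of the tests of the low H3K4me3 share of 5hmC sites in undamaged library 1 and day 5 library 1, that of CpG-dense fragments was chosen before and the others after the result was seen. The number of sites does not explain it, since day 3 library 1 with fewer sites had a share 5.99 points above day 5 library 1, nor does mapping quality, with a gap of 3.30 points at all mapping qualities. Loss of CpG-dense fragments could, narrowly, since 29.5% of sites outside peaks lay at the CpG-densest places in the higher of the 2 libraries and 29.7 to 31.5% in the other 4. Between these 2 libraries and the other undamaged and day 5 libraries edgeR called 321 promoters (68 higher and 253 lower) and 527 peaks, which restates the pattern and does not test it. No biological explanation was tested.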
